A study of Homo sapiens with 44 samples.

How the data were processed

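Alpha, beta and exocrine (acinar and duct) cells were sorted by FACS with surface antibodies from dispersed human islets of 6 donors, per the labels' protocols. Of 44 labelled samples 27 had processed files analysed here: 10 for H3K4me3, 9 for H3K27me3 and 8 for RNA. The 17 input samples were not used here. Groups came from the labels, and samples are named by cell type, assay and replicate. Alpha and beta replicates with the same number within an assay came from the same donor; 1 donor had both histone marks in all 3 cell types. In 4 of the 27 files the track line disagreed with the labels. The labels were followed, and the RNA comparisons were repeated without the 3 RNA libraries among them. Those were alpha replicate 2, beta replicate 2 and exocrine replicate 1, all from the same donor. Leaving them out therefore also removed that donor and left 1 exocrine library.

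H3K4me3 regions were called per library with GLITR at a false discovery rate of 5%, per the file headers, and each region's score is the authors' own value. H3K27me3 spans were called per library with STAR, in windows of 5000 bp moved by 1000 bp at a false discovery rate of 0.005, per the file headers, again with a score by the authors. STAR here is that span caller, not the RNA aligner of the same name. The submitters' processing notes name CASAVA 1.7 and the hg18 build, and coordinates are on that build and start from 1. Scores were used only to rank regions within a list. The reads behind each list, the role of the inputs and the handling of duplicates were not stated in the file headers, so list lengths can carry differences in depth.

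The RNA files hold RPKM per exon, intron and transcript from RUM, as deposited by the authors, per the file headers. Libraries were made from total RNA, per the labels' protocols, and strand was not recorded, so sense and antisense reads cannot be told apart. For each library 1 constant turned 99.6 to 100% of the low values (under 20 reads, tolerance 0.1 read) into whole reads, which gave a scaling total of 38.2 to 65.0 M reads. Reads in gene exons made up 9.71, 26.0 and 21.0% of that total in alpha replicates 1 to 3, 11.1, 12.5 and 23.1% in beta replicates 1 to 3 and 32.3 and 22.8% in exocrine replicates 1 and 2. RPKM divides by all scaled reads and does not adjust for this share, so a library with a low share reads low for most genes.

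Transcripts were matched to symbols by RefSeq accession with a RefSeq table of GRCh38.p14, used for names only: 33681 of 35160 matched (95.8%). Genes on Y and the X-inactivation transcripts were left out, which left 21555 genes. PAX4 and SETD1B had no matched transcript. Each gene was represented by its transcript with the highest mean. Genes with at least 1 RPKM in 2 of the 8 libraries (13741) were tested with limma 3.58.1 in R 4.3.3 with a trend on log2(RPKM + 0.5), in 1 fit of all 8 libraries; fold changes are on that scale, which understates the change of low genes. P-values were adjusted by Benjamini and Hochberg, threshold 0.05. Donors are the replicates, but the main fit had no donor term. Its p-values measure the spread between libraries of a cell type, not the spread of paired differences within donors. Whether donors paired the libraries came from the labels; the correlation of deviations from the group mean was 0.668, -0.0289 and 0.521 in the 3 pairs.

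The 20 gene lists were alpha cell, beta cell, delta with PP and epsilon cell, pan-endocrine, acinar, duct, endothelial, mesenchymal, immune, dissociation and stress, unfolded protein response, cell cycle, HOX, developmental regulators, WNT, TGF-beta and BMP, Polycomb and Trithorax, housekeeping, neuronal and nutrient sensing genes. Groups, most tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. Alternatives added after the data were seen were limma-voom on recovered reads, intron subtraction, the fits without the libraries whose track lines disagreed, and the settings that leave out or single out a donor or trim lists to one number of marked promoters. For the promoter sets, fry was chosen over camera as the leading test after the data were seen, and the tests of overlap between lists and promoter sets were added then. Lists were tested with camera (preset correlation 0.01, and estimated) and fry. The rule named the 8 largest changes in each direction between alpha and beta cells among genes past the threshold with one sign in all 3 pairs and at least 5 RPKM, the 5 largest in each direction for each exocrine comparison among genes past the threshold whose groups did not overlap, 2 to 4 members with the largest change of each list of pancreatic cell types described, the 6 promoters with the largest RNA change for each mark and for bivalency in each direction, and a few genes of alpha and beta cell identity always, among them GCG, INS, PDX1, MAFA and IRX2. Members of a list that a sentence describes could be named too.

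A promoter was marked when a region of the library overlapped the 1000 bp on either side of any RefSeq start of the gene by at least 1 bp. A cell type was called H3K4me3-marked with 3 of 4 alpha or beta libraries or both exocrine libraries, and H3K27me3-marked with 2 of 3. Numbers per library and Jaccard indices were compared by exact two-sided permutation of the labels, with a smallest p of 0.0286 for 4 against 4 and 0.1 for 3 against 3; the bivalent difference was tested over 1400 arrangements, and over 64 swaps within donors. Overlaps of lists with promoter sets used one-sided Fisher's exact tests over all 21555 promoters, adjusted over 160 tests; overlaps with bivalent sets were tested among the promoters with H3K27me3 in the same cell type, adjusted over 60 tests, since a bivalent promoter has that mark by definition.

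The steps were tested on simulated data. On 13741 simulated genes the limma step recovered 2, 27, 40 and 46 of 50 genes changed by 1, 2, 3 and 4 on the log2 scale between alpha and beta cells, with 7 unchanged genes called; between alpha and exocrine cells it recovered 1, 16, 35 and 42, and between beta and exocrine cells 2, 19, 34 and 42. For alpha against beta cells a list of 30 genes shifted by 1 gave a camera p of 1.7e-20, and 5 of 200 random lists fell under 0.05. The promoter step placed no wrong mark at 2000 simulated promoters and recovered 100 of 100 and 60 of 60 separating promoters of 4 against 4 libraries. Those promoters were marked in every simulated library of one group and none of the other. Their recovery therefore checks the code and not how the step does with uneven lists. Alternatives covered the pseudocount (0.1 and 1), the filter, quantile normalization, the donor as a block, each library left out, the promoter window, stricter and equally long lists and the rule for consensus. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.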

Results

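Pancreatic islets hold glucagon-producing alpha cells and insulin-producing beta cells, and islet preparations also carry exocrine cells, which are the acinar and duct cells of the digestive pancreas. The series profiled these 3 sorted cell types from 6 donors. H3K4me3, a histone mark found at active or poised promoters, was mapped in 4 alpha, 4 beta and 2 exocrine samples. H3K27me3, the mark laid down by Polycomb repressive complex 2 over silenced genes, was mapped in 3 samples of each type, and RNA was sequenced in 3 alpha, 3 beta and 2 exocrine samples. The H3K4me3 lists held 20019 to 39022 regions per library and the H3K27me3 lists 33338 to 47198 spans. Read numbers behind the lists were not given in the sources used here. The RNA files were scaled to 38.2 to 65.0 M reads per library. The study's title concerns the plasticity of alpha cells toward the beta cell state, so the comparison of alpha with beta cells comes first.

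H3K27me3 lay on the genes of the opposite hormone cell. The promoter of GCG, which encodes glucagon, was inside an H3K27me3 span in 3 of 3 beta and 3 of 3 exocrine libraries and in 0 of 3 alpha libraries, while H3K4me3 was called there in 3 of 4 alpha and 0 of 4 beta libraries. INS, which encodes insulin, showed the opposite, with H3K27me3 in 3 of 3 alpha, 0 of 3 beta and 2 of 3 exocrine libraries and H3K4me3 in 0 of 4 alpha and 3 of 4 beta libraries. IAPP, which encodes the peptide co-secreted with insulin, and the beta cell transcription factor genes MAFA and PDX1 were H3K27me3-marked in 3 of 3 alpha and 0 of 3 beta libraries. IRX2, an alpha cell transcription factor gene, had H3K4me3 in 4 of 4 alpha and 0 of 4 beta libraries and H3K27me3 in 0 of 3 alpha and 3 of 3 beta libraries.

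Positions are in the hg18 build. GCG lies on the minus strand of chromosome 2 from 162707631 to 162717160, and the H3K4me3 regions over its start in alpha cells fell between 162713116 and 162717567. The beta cell H3K27me3 spans over GCG were 68000 to 78000 bp wide, between 162693001 and 162772000, and covered the whole gene with its introns. INS lies on the minus strand of chromosome 11 from 2137585 to 2139015. It was covered in alpha cells by spans of 53000 to 142000 bp between 2010001 and 2152000, all 3 of which also took in IGF2. PDX1, on chromosome 13 from 27392168 to 27398451, had an H3K27me3 span of 39000 to 187000 bp in each alpha library, beside H3K4me3 in 4 of 4 alpha, 4 of 4 beta and 2 of 2 exocrine libraries.

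**Figure D1:**
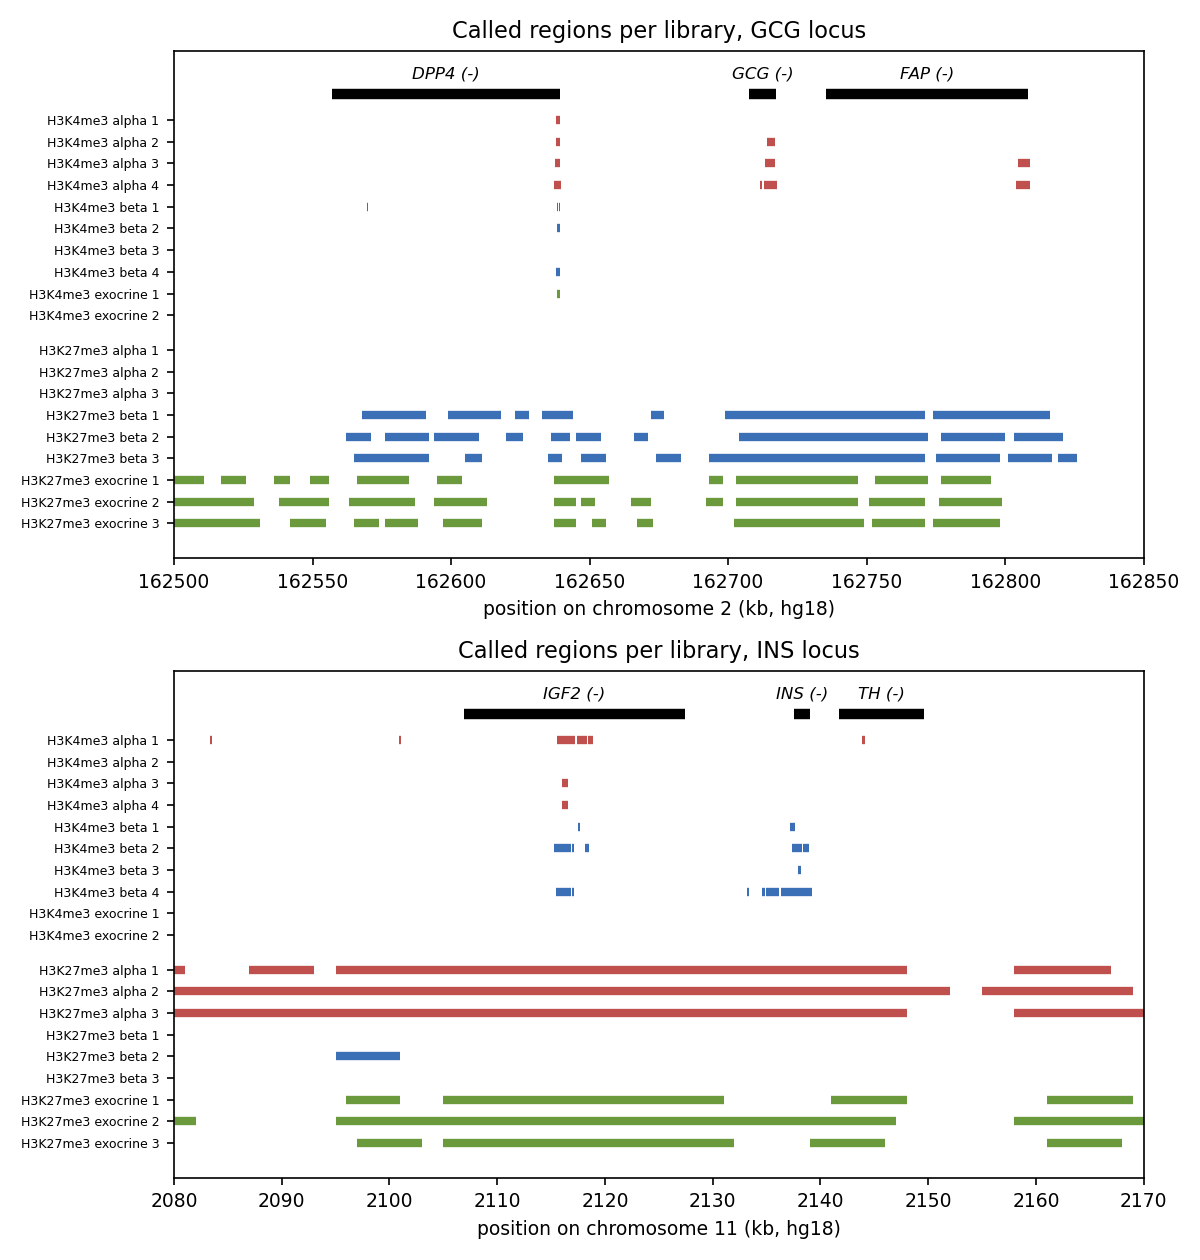
Regions called in each library around GCG (chromosome 2) and INS (chromosome 11), with position in kb (hg18) on the horizontal axis and 1 line per library; black bars are genes with their strand. H3K27me3 spans cover GCG in 3 of 3 beta libraries and no alpha library, and INS in 3 of 3 alpha libraries and no beta library.

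Across 21555 promoters, 386 had H3K27me3 in every alpha and no beta library and 264 in every beta and no alpha library. Of the 34 beta cell genes fixed beforehand, 14 were among the 386, against 0.609 expected (one-sided Fisher's exact test, adjusted p = 4.4e-14 over 160 tests). They were INS, IAPP, MAFA, PDX1, ADCYAP1, PCSK1, HADH, RGS16, NPTX2, TGFBR3, DLK1, IGF2, SIX2 and WSCD2. Of the 27 alpha cell genes, 7 were among the 264 (0.331 expected, adjusted p = 1.1e-06 by the same exact test), namely GCG, IRX2, DPP4, FAP, HIGD1A, KCNJ3 and PTPRT. LDHA, which encodes a lactate dehydrogenase subunit, and FSTL5 were also in the 264, each with H3K4me3 in 4 alpha and 3 beta libraries. The other 9 ways to split these 6 libraries gave at most 49 such promoters against 650, but 10 splits allow no share under 0.1. Neighbouring genes can share a span, so they are not independent in these tests.

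H3K4me3 separated the cell types at fewer promoters, though with 4 libraries of each type the rule is stricter than with 3. It was present in every alpha and no beta library at 50 promoters and the reverse at 1, LRRTM3, a postsynaptic adhesion gene that had H3K27me3 in 3 of 3 alpha and 0 of 3 beta libraries. The reverse set needed the mark in beta replicate 1, whose list marked the fewest promoters, 10041, so the 50 and the 1 do not compare evenly. The 50 included 4 of the 27 alpha cell genes, CD36, GPR119, IRX1 and IRX2 (one-sided Fisher's exact test, adjusted p = 9.9e-06). MBOAT4, which encodes the ghrelin acyltransferase, F10 and NSG2 were also among the 50. As many separating promoters came from 2 of the 35 splits of the 8 libraries, the highest other split giving 107, and swapping labels within the 4 donors gave at most 26. Leaving out a library loosens the rule, so the number can only stay or rise. In the alpha direction it was 121 without alpha replicate 2 and 76 without beta replicate 2, and higher still without beta replicate 4.

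Alpha libraries had H3K4me3 on 13753.5 ± 735 promoters (SD, n = 4) and beta libraries on 12224 ± 1608 (n = 4), a difference of 1529 that stayed within the spread (exact two-sided permutation p = 0.171). The 2 exocrine libraries had 12275 and 13007. H3K27me3 was on 5218 ± 129 promoters in alpha (n = 3) and 4831 ± 62.0 in beta cells (n = 3), with no overlap between the groups. The exact permutation p of 0.1 is the smallest that 3 against 3 can give. Exocrine libraries had H3K27me3 on 5361 ± 216 promoters (n = 3), 337 more than the mean of the 6 alpha and beta libraries (exact permutation p = 0.0833). With the promoter window at 2500 bp on each side the difference of islet minus exocrine was -540 (exact permutation p = 0.0357), and with lists of equal length it was 146.

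**Figure D2:**
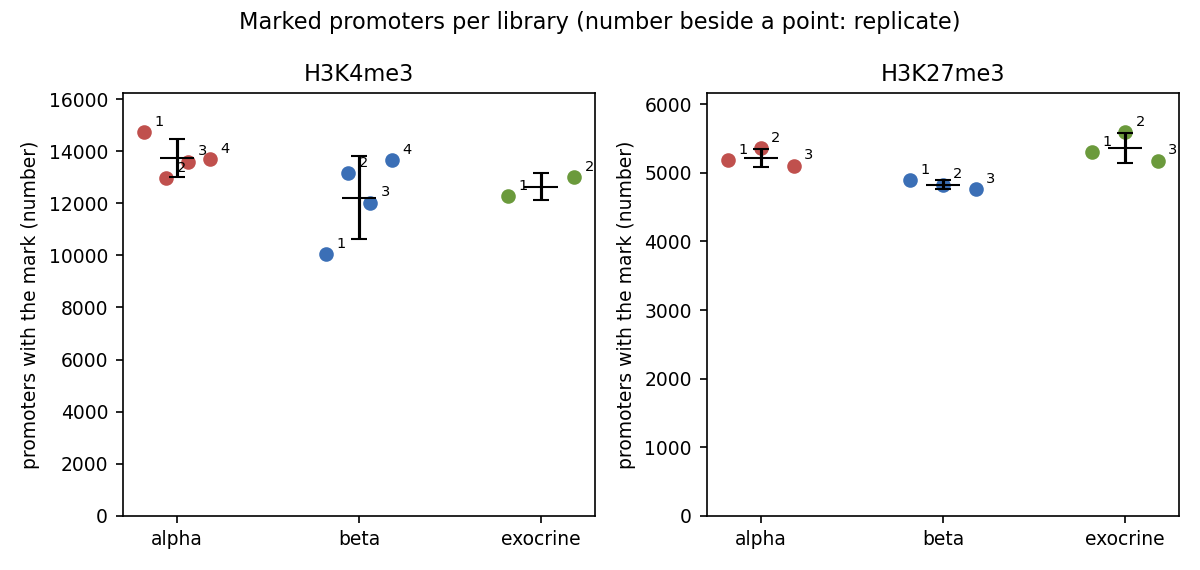
Number of promoters with H3K4me3 (left) and H3K27me3 (right) in each library of alpha, beta and exocrine cells; the digit beside a point is the replicate, and black lines are the mean and SD of each group. Beta H3K4me3 replicate 1 lies lowest with 10041 promoters, and the 3 beta H3K27me3 libraries, from 4769 to 4893, lie below the 3 alpha libraries.

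Promoters called for both marks in a cell type, here called bivalent, were more numerous in alpha than in beta cells. The marks were called in separate libraries of sorted cells, and only 1 donor gave both marks. That both marks lay on the same chromosomes of the same cells was therefore not shown. Alpha cells had 1782, beta cells 894 and exocrine cells 1108. Alpha and beta cells shared 693, and 1089 were bivalent in alpha alone, of which 472 had H3K4me3 alone, 548 H3K27me3 alone and 69 neither mark in beta cells. The 1089 held 12 of the 20 beta cell genes with H3K27me3 in alpha cells, against 4.22 expected among the 5163 promoters with that mark (adjusted p = 0.0101 over 60 one-sided Fisher's exact tests), among them PDX1, ADCYAP1, HADH, PCSK1, RGS16, NPTX2 and TGFBR3, all with H3K4me3 in beta cells too. They also held 19 of 85 H3K27me3-marked developmental regulators of other lineages, such as CDX2, NKX2-1 and FOXD3 (17.9 expected), 9 of 31 WNT ligands and receptors (6.54 expected) and 7 of 22 neuronal genes (4.64 expected), none of which passed the same exact test. A further 201 promoters were bivalent in beta alone, including DPP4, LDHA, FSTL5, IGFBPL1, SERPINE2 and VIM. The 201 held 4 of the 13 alpha cell genes with H3K27me3 in beta cells (0.542 expected, adjusted p = 0.0469 by the same exact test).

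The difference of 888 bivalent promoters had an exact two-sided permutation p of 0.0171 over 1400 arrangements of the labels, while swaps within donors, the replicate block, gave an exact p of 0.125 for the same 888. With the H3K4me3 of 1 donor at a time and the H3K27me3 of all libraries of each type, alpha cells had more in 4 of 4 donors. The differences were 300, 2085, 936 and 273, so 1 donor held the largest gap. They share the same H3K27me3 calls and are not donor replicates of bivalency. The donor with the largest gap was the only one with both marks. By its libraries alone alpha cells had 2806 bivalent promoters, beta cells 688 and exocrine cells 1776. It also had the longest alpha and the shortest beta H3K4me3 list. Without that donor's H3K4me3 the difference was 517 (exact p = 0.07), and with lists trimmed by score to the same number of marked promoters it was 194 (exact p = 0.0686).

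Against exocrine cells, H3K27me3 in exocrine cells lay on endocrine genes and in islet cells on acinar genes. It was in every alpha and beta but no exocrine library at 315 promoters and the reverse at 603. The 603 held 12 of 26 genes shared by endocrine cells (0.727 expected, one-sided Fisher's exact test, adjusted p = 1.1e-10), including NEUROD1, PAX6, NKX2-2, INSM1, RFX6, CHGA and ABCC8. They also held 6 of 27 alpha cell genes (adjusted p = 0.0017) and 5 of 34 beta cell genes (adjusted p = 0.024), by the same exact test. The 315 held 10 of 35 acinar genes (0.511 expected, adjusted p = 2.7e-09 by the same exact test), including the acinar regulators PTF1A, RBPJL, NR5A2 and GATA4 and the enzyme genes PRSS1, PNLIP and PNLIPRP2, and 5 of 40 TGF-beta and BMP pathway genes (adjusted p = 0.0041), CHRD, GDF10, ID3, SMAD6 and TGFBR2. Of 25 duct genes 2 were among the 315, KRT7 and SLC4A4, which did not pass (adjusted p = 0.315 by the same exact test). All 39 HOX promoters had H3K27me3 in each of the 3 cell types. The count of 918 was higher than in any other of 84 splits of the 9 libraries, which reached 264. H3K4me3 was in every islet cell and no exocrine library at 89 promoters and the reverse at 50.

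The H3K27me3 maps were more alike within than between alpha and beta cells. The mean Jaccard index in bp was 0.615 within a type and 0.479 between alpha and beta (difference 0.135, exact permutation p = 0.1, the smallest possible), and islet cells shared 0.408 with exocrine cells. For H3K4me3 the values were 0.527 within and 0.510 between (difference 0.0177, exact permutation p = 0.171). Without alpha replicate 1, 3 or 4 the H3K4me3 difference was below 0, the lowest -0.0129.

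Among RNAs, MBOAT4, MUC13 and CD36 were higher in alpha cells and ACP3 was higher in beta cells. MBOAT4 averaged 11.1 ± 3.34 RPKM in alpha and 1.15 ± 0.615 in beta cells (log2 fold change 2.84, SE 0.39), and MUC13, a cell surface mucin gene, 13.1 ± 3.04 and 1.47 ± 0.274 (2.77, SE 0.40). CD36, a fatty acid transporter gene, had a log2 fold change of 2.26 and ACP3, an acid phosphatase gene, one of -2.01; both were named after their values were seen. All 4 differed the same way in 3 of 3 donor pairs with a limma adjusted p of 0.0446, and they were the only genes past 0.05 of 13741 tested, with 589 at an unadjusted p under 0.05. MBOAT4 and CD36 also had H3K4me3 in every alpha and no beta library.

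GCG and INS had larger log2 differences than these 4 genes and larger standard errors. GCG averaged 5952 ± 4668 RPKM in alpha and 267 ± 276 in beta cells (log2 fold change 4.73, SE 1.24, limma adjusted p = 0.287), and INS 355 ± 184 and 3090 ± 1535 (-3.18, SE 1.13, adjusted p = 0.727), each in the same direction in 3 of 3 donor pairs. IRX2 was at 8.85 ± 4.71 and 1.13 ± 0.796 RPKM (2.51, adjusted p = 0.142) and MAFA at 2.15 ± 1.27 and 22.7 ± 18.1 (-2.76, adjusted p = 0.380). PDX1 was below the expression filter, at a mean of 0.547 RPKM in alpha, 1.03 in beta and 0.518 in exocrine cells.

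With the donor as a replicate block, 476 genes passed, 264 higher in alpha and 212 in beta cells, including all 4 above. In that fit GCG had an adjusted p of 2.3e-14, INS 6.0e-07, IAPP 0.00198, IRX2 1.8e-12, MAFA 3.4e-08 and ADCYAP1 2.6e-11. The blocked limma fit took every gene's spread from the overall trend, with no spread of its own, so these p-values are less firm than their size. The scaling also moved the count and its split: quantile normalization gave 58 genes (31 higher, 27 lower) and limma-voom on the recovered reads 57 (24 higher, 33 lower), with the median of all genes shifted by -0.11 and -0.23. Leaving out alpha replicate 1 gave 101 genes and beta replicate 1 gave 34. Without beta replicate 3 there were 2, and without any of the other 5 libraries in turn, or without the 3 RNA libraries whose track lines disagreed with the labels, 0, with 266 to 522 at an unadjusted p under 0.05.

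**Figure D3:**
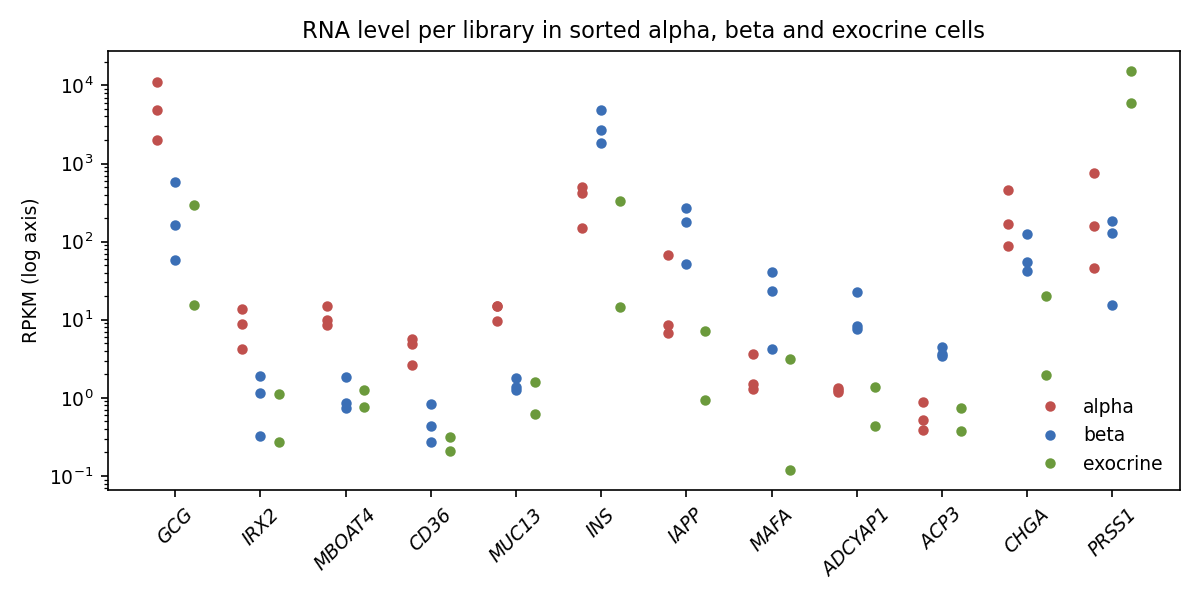
RPKM (log axis) of named genes in each RNA library of sorted alpha, beta and exocrine cells, 1 point per library. GCG lies higher in each alpha library than in any other, and INS and ADCYAP1 lie higher in each beta library than in any other.

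The alpha cell list was higher in alpha cells as a group. Of 26 tested members, 22 were higher when adjusted over the list alone and 1, CD36, over all genes (22 over all genes with the replicate block), with a median log2 fold change of 2.05. GC, at 58.6 RPKM against 2.50, TM4SF4, at 68.6 against 4.69, and LOXL4 had values of 4.47, 4.13 and 3.79. Of 32 beta cell genes, 21 were lower in alpha cells when adjusted over the list alone and 0 over all genes (18 with the replicate block), with a median of -1.59. The largest after INS were IAPP at -3.07, MAFA at -2.76 and ADCYAP1 at -2.75. Both passed camera with a preset correlation (adjusted p = 1.2e-35 and 2.8e-38), and both had an adjusted p of 0.103 with an estimated correlation. The directional test of fry gave both an adjusted p of 0.151. No list of the 20 passed with an estimated correlation in any comparison of the RNA. Directional fry passed no list between alpha and beta or alpha and exocrine cells. Between beta and exocrine cells it passed the acinar, neuronal and beta cell lists (adjusted p = 0.0154, 0.0154 and 0.0366).

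With the preset correlation 6 other lists passed between alpha and beta cells. The immune list was lower in alpha cells (9 tested, median -1.16, adjusted p = 1.7e-09, and adjusted p = 0.185 with an estimated correlation), with 2 members lower when adjusted over the list alone and 0 over all genes (5 with the replicate block). The 2 were C1QB and LAPTM5, macrophage genes, at 5.03 and 1.88 RPKM in beta cells. Neuronal genes were lower too (16 tested, median -0.27, adjusted p = 0.000103, and 0.103 with an estimated correlation), with 4 members passing when adjusted over the list alone, among them SLC17A6, GAD1 and NEFM, and 0 over all genes (5 with the replicate block). The immune and neuronal genes named here were picked after their values were seen. The acinar list was higher in alpha cells (35 tested, median 1.03, adjusted p = 0.0292, and 0.897 with an estimated correlation), with 0 members past either adjustment and PRSS1 at 319 ± 380 RPKM in alpha and 109 ± 85.5 in beta cells. It did not pass without alpha replicate 1 or 2 or beta replicate 1 or 3, and without alpha replicate 2, where acinar genes were at 7.04% of the exocrine level, its median was 0.08 (adjusted p = 0.557). HOX genes (median -0.31, adjusted p = 0.00638, estimated correlation 0.302), developmental regulators (-0.20, adjusted p = 0.00032, estimated correlation 0.281) and the WNT list (-0.09, adjusted p = 0.0394, estimated correlation 0.677) passed downward with 0 members past either adjustment. The WNT list did not pass with the replicate block (adjusted p = 0.068). Intron density over genes with H3K27me3 alone was 0.423, 0.397 and 0.400 RPKM in alpha replicate 1 and beta replicates 1 and 2 and 0.278, 0.327 and 0.293 in alpha replicates 2 and 3 and beta replicate 3, so low values over such genes differed by library as well as by cell type. The HOX and developmental lists did not pass without alpha replicate 2 or without beta replicate 2.

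The other 12 lists did not pass. Their medians were 0.18 for delta, PP and epsilon genes, 0.19 for pan-endocrine, -0.03 for duct, -0.24 for endothelial, -0.34 for mesenchymal, -0.03 for stress, -0.18 for unfolded protein response, 0.34 for cell cycle, 0.01 for TGF-beta, 0.03 for Polycomb and Trithorax, 0.27 for housekeeping and 0.38 for nutrient sensing genes. Within the delta, PP and epsilon list PPY, the hormone gene of PP cells, averaged 197 ± 132 RPKM in alpha and 31.8 ± 39.8 in beta cells, higher in alpha in 3 of 3 donor pairs (3.08, limma adjusted p = 0.863, and 0.0043 with the replicate block). The median had another sign than the camera direction for the delta, TGF-beta and Polycomb lists, and than the mean for the mesenchymal, TGF-beta and duct lists.

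Acinar enzyme RNAs were far lower in alpha than in exocrine cells, and endocrine RNAs higher. Of 35 acinar genes, 24 were lower over all genes and 34 when adjusted over the list alone (median -5.31). PNLIP, pancreatic lipase, was at 6111 ± 3955 RPKM in exocrine cells (n = 2) and had a log2 fold change of -6.99 (SE 1.63, limma adjusted p = 0.0385), and CELA2A, CTRC, AMY2A and CPA1 had -6.46, -6.09, -6.06 and -6.02. Duct genes were lower as well, 7 of 24 over all genes and 13 when adjusted over the list alone, led by KRT7 (-3.80, adjusted p = 0.00834) and MMP7 (-3.25, adjusted p = 0.012). Of 26 alpha cell genes, 12 were higher over all genes and 23 over the list alone; GCG (6.10, SE 1.38, adjusted p = 0.0342), CNTN1 (3.88), FAP (3.54), RGS4 (3.37) and PCSK2 (3.34) were the highest named by the rule. Pan-endocrine genes had 2 and 16 of 25, and the stress list had 4 lower over all genes, IER2, MYC, CXCL8 and CCL2, and 8 adjusted over the list alone; these 4 were named after their values were seen.

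Between alpha and exocrine cells 430 genes passed, 89 higher and 341 lower in alpha cells, and 1761 with the replicate block. The exocrine RNA libraries shared a sequencing run with no other RNA library, so run and cell type cannot be told apart. Leaving out the libraries whose track lines disagreed also removed 1 donor and left 1 exocrine library. Quantile normalization gave 528 higher and 622 lower genes and limma-voom 2884 and 470, the latter with the median of all genes shifted by 0.59. Without the libraries whose track lines disagreed 20 genes were left, and leaving out 1 library gave 108 to 959, the lowest without exocrine replicate 1. The lists that passed camera with the preset correlation were the alpha cell (adjusted p = 7.9e-24), beta cell (0.00421), pan-endocrine (3.8e-14) and neuronal lists (0.0245) upward and the acinar (3.4e-37), duct (1.6e-13), stress (1.1e-06) and unfolded protein response lists (0.00045) downward. Their adjusted p with an estimated correlation was 0.23 for the alpha cell, acinar, duct and neuronal lists, 0.368 for the pan-endocrine and stress lists, 0.856 for the unfolded protein response and 0.858 for the beta cell list. Of the other 12 lists the delta, PP and epsilon cell list came nearest (adjusted p = 0.111).

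Beta cells differed from exocrine cells in endocrine, acinar and duct genes, with IAPP and INS at the top. IAPP (log2 fold change 5.36, SE 1.22, limma adjusted p = 0.0352) and INS (5.33, SE 1.26, adjusted p = 0.0415) were the highest, followed by CDKN1C, a cell cycle inhibitor gene, at 3.52, SYT13 at 3.49 and ADCYAP1 at 3.15. Of 32 beta cell genes, 10 were higher over all genes and 28 when adjusted over the list alone (median 2.17), and of 25 pan-endocrine genes 1 and 17. Of 35 acinar genes, 27 were lower over all genes and 33 over the list alone (median -6.43), with PNLIP at -8.09, CELA2A at -7.53, AMY2A at -7.28, CPA1 at -7.05 and PRSS1 at -7.05; duct genes had 6 and 15 of 24, with KRT7 at -4.00. The amylase, trypsinogen, elastase and carboxypeptidase genes have near-identical copies and INS overlaps a read-through transcript with IGF2, so reads can be shared among them and their single values are uncertain.

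In total 404 genes passed between beta and exocrine cells, 70 higher and 334 lower in beta cells, and 2017 with the replicate block. Quantile normalization gave 553 higher and 744 lower and limma-voom 3097 and 380 with a median shift of 0.85. Without the libraries whose track lines disagreed 19 genes were left, and leaving out 1 library gave 128 to 807, the lowest without exocrine replicate 2. Camera with the preset correlation passed the alpha cell (adjusted p = 0.0125), beta cell (2.3e-25), pan-endocrine (1.4e-13), immune (7.6e-05), HOX (0.00887) and neuronal lists (1.0e-06) upward and the acinar (5.0e-38), duct (1.0e-11), stress (8.0e-05), unfolded protein response (0.00922) and housekeeping lists (0.031) downward. With an estimated correlation their adjusted p was 0.0597 for the neuronal, 0.194 for the acinar, 0.204 for the beta cell, 0.291 for the duct, 0.335 for the pan-endocrine, immune and HOX, 0.437 for the stress and 0.741 for the alpha cell, unfolded protein response and housekeeping lists. The remaining 9 lists had medians from -0.32, for nutrient sensing, to 0.35, for endothelial genes.

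Genes with H3K4me3 alone at the promoter were the most expressed in each cell type. In alpha cells 74.9 ± 11.2% of such genes reached 1 RPKM or more (SD, n = 3 libraries), against 31.2 ± 4.01% of bivalent genes, 11.5 ± 4.60% of genes with H3K27me3 alone and 24.3 ± 1.15% of genes with neither mark. Beta cells had 75.4 ± 8.22%, 36.6 ± 6.08%, 19.4 ± 5.28% and 31.9 ± 1.84% (n = 3), and exocrine cells 76.6 ± 2.83%, 35.2 ± 3.77%, 11.8 ± 1.79% and 26.3 ± 1.62% (n = 2). In each of the 8 libraries the median log2 value was higher for H3K4me3 alone than for both marks and higher for both marks than for H3K27me3 alone. These are differences across genes, which are not replicates.

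**Figure D4:**
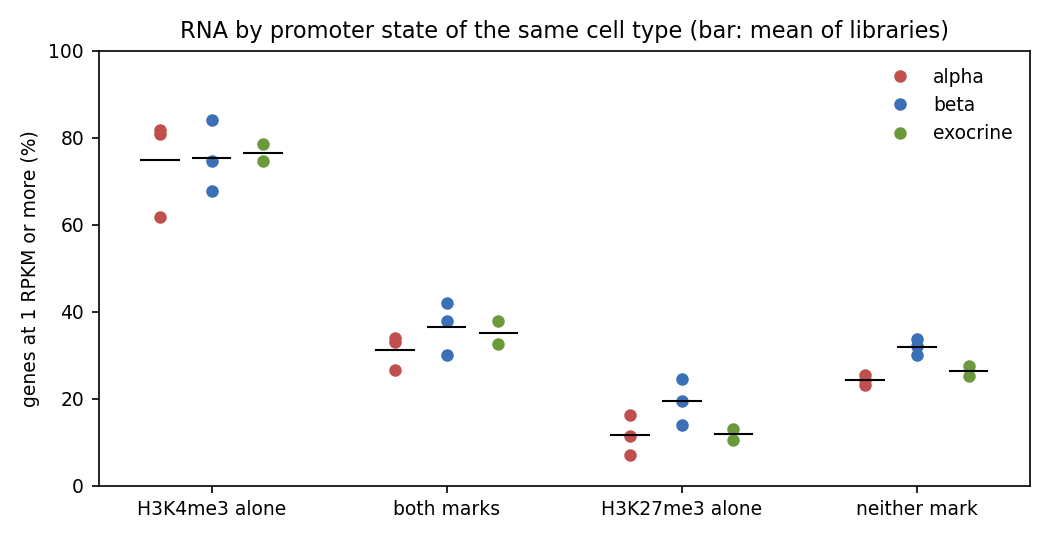
Percent of genes at 1 RPKM or more in each RNA library, by the marks at the promoter in the same cell type; points are libraries and black bars group means. In alpha cells the means are 74.9% for H3K4me3 alone, 31.2% for both marks, 11.5% for H3K27me3 alone and 24.3% for neither.

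For 2 of the 3 sets of promoters that a mark separated between alpha and beta cells, RNA differed in the matching direction. Of 233 tested genes with H3K27me3 in every alpha and no beta library, 182 had a negative log2 fold change (median -0.37, fry adjusted p = 0.0449), with 35 lower when adjusted over the list alone and 0 over all genes. The 26 tested genes with H3K4me3 in every alpha and no beta library had a median of 0.51 (fry adjusted p = 0.029), with 8 higher over the list alone and 2, MBOAT4 and CD36, over all genes. The 119 genes with H3K27me3 in every beta and no alpha library had a median of 0.42 and 33 higher over the list alone, at a fry adjusted p of 0.0928, or 0.0475 with the replicate block. The 576 genes bivalent in alpha alone (median -0.15, fry adjusted p = 0.260) and the 123 bivalent in beta alone (median 0.36, 0.253) did not pass. With an estimated correlation, camera gave an adjusted p of 0.0197 for the first of these lists and 0.0251 for the second, and the marks and RNA shared some donors, so the lists are not fully independent of the RNA.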

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

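The counts of splits for promoters that separate groups and the comparisons over donors with like lists and over promoters with H3K4me3 in both types were tests chosen only after the result was seen, as were the alternatives that leave out the donor with both marks, trim lists to one number of marked promoters, subtract intron density or use limma-voom.

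Alpha H3K4me3 replicate 1 had 39022 regions, far from the other 3 alpha libraries, whose highest was 26549. Chance alone would set a library apart in about 1 in 20 of the 8 combinations of group and measure tested this way. Those were related measures of the alpha and beta H3K4me3 libraries only. Introns, which the comparisons did not use, held 65.1, 70.4 and 54.5 of every 100 exon and intron reads in alpha, beta and exocrine RNA.

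Alpha cells had 888 more bivalent promoters than beta cells. Chance labelling gave as large a difference in 24 of 1400 arrangements, though the highest other reached 1023. Unequal list length alone is argued against by the 717 left with equally long lists. Without the H3K4me3 of the donor with the longest alpha and shortest beta list, 517 were left. Fewer were left without that donor in either mark, and the difference lost its p in both settings. How much of the difference came from that donor therefore cannot be told. Beta lists that mark fewer promoters are a candidate cause of part of the size. The mean difference was 286.5 in the 2 donors with like numbers, against 2085 and 936 in the others. Whether such lists are the whole cause cannot be told. The 300 and 273 of those 2 donors and the 290 left among promoters with H3K4me3 in both types go against that. All of these rest on the same H3K27me3 libraries, though, and another of the 10 splits of those libraries reached 244. The 194 left with lists trimmed to the same number (522 against 328) met a bound for the whole cause written before that value was seen, but trimming lowered both totals and took the ratio of alpha to beta only from 1.99 to 1.59, and the 290 was chosen afterwards. Of the 888, H3K4me3 missing in the other type made the larger part (548 against 18). H3K27me3 at promoters with H3K4me3 in both types made the 290 (472 in alpha alone against 182 in beta alone, a ratio of 2.59). Beta libraries had more H3K27me3 overall (40121 spans and 742 Mb against 34795 and 627 Mb). At promoters, where bivalency was called, alpha libraries had more, a mean of 5218 against 4831, the same direction as the 472 against 182. A biological difference stays open, with its size not settled.

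The RNA libraries differed along an axis other than cell type. The split of alpha replicate 1 with beta replicates 1 and 2 against the other 3 called 7550 genes as RPKM, 7180 of them lower in the first, against 4 in the real split; 2 of 10 splits gave 4 or more, and 10 splits are too few for a share under 0.05, whereas the splits that part all 3 donor pairs, like the real one, gave at most 1. Those 3 libraries had the lowest share of reads in exons, and the split called 787 with quantile normalization (517 higher, 270 lower) and 2579 with limma-voom (2262 higher, 317 lower), so a low share that RPKM does not adjust for is a candidate cause of the common direction. The 7466 genes left after subtracting intron density decide nothing about an added uniform background, since without rescaling the subtraction could not narrow the gap. Intron density was 1.02 to 1.06 times as high over H3K4me3 promoters as over H3K27me3 promoters in those 3 libraries and 1.30 to 1.44 times in the other 5, under the bound of 1.5 set beforehand, which goes with genomic DNA as the main source of intron reads and against unspliced transcripts as the main source, though the excess in the 5 leaves a smaller part from transcripts open and no biological explanation was tested.

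Acinar RNAs were present in alpha and beta libraries. Their median level was 0.621, 7.04 and 1.59% of the exocrine level in alpha replicates 1 to 3 and 0.334, 1.16 and 1.75% in beta replicates 1 to 3, over 29 genes of at least 100 RPKM in exocrine cells. A uniform background is argued against, because levels followed the exocrine ones with a Spearman rho across genes of 0.779 or more in each library. Exocrine cells or their RNA in the sorted cells may be the source, since the widest interquartile range of the log2 ratio was 1.62, under the bound of 2, with PRSS1 at 319 RPKM in alpha and 10693 in exocrine cells. The sort would remove most such cells, and expression by the islet cells themselves was not tested. Hormone RNAs differed between the exocrine libraries. GCG was at 293 RPKM in exocrine replicate 1 and 15.6 in replicate 2, and INS at 332 and 14.6. The source of this gap was not tested, and the changes of GCG and INS against exocrine cells depend on it.

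H3K4me3 separated alpha from beta cells at 51 promoters, as many as in 2 of 35 splits with 107 as the highest other, so chance cannot be excluded. H3K27me3 did so at 650 in 1 of 10 splits, with 49 as the highest other, and 10 splits are too few for a share under 0.05. Islet and exocrine cells were separated by H3K27me3 at 918 promoters in 1 of 84 splits, with 264 as the highest other. Those splits ignore that alpha, beta and exocrine libraries came from the same donors. Swaps within donors were not run here, so chance is not excluded.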

How the results depend on the processing

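Tests chosen only after the result was seen were limma-voom on recovered reads, subtraction of intron density, the fits without the libraries whose track lines disagreed, and the settings without the donor with both marks, with 1 donor's H3K4me3 or with lists trimmed to one number of marked promoters. Of 1644 values for named genes 1326 kept their side of the threshold and direction, 155 lost the threshold, 149 gained it and 14 moved; of 600 for single lists 513 did, 56 lost it, 8 gained it and 23 moved; none past the threshold changed direction. Exon reads ranged from 6.19 to 16.9 M per RNA library, and how far depth limited the calls was not tested. Causes were not tested except where fewer samples or another spread show them.

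Genes past the threshold between alpha and beta cells numbered 4, and 0 with a pseudocount of 0.1, the median over transcripts, alpha and beta libraries only, intron density subtracted, or the 3 libraries whose track lines disagreed left out; 1 with no filter, 58 with quantile normalization, 57 with voom, 476 with the replicate block and 0 to 101 without 1 library. Against exocrine cells the 430 alpha genes became 272 with no filter, 1150, 3354 and 161 with quantile normalization, voom and intron subtraction, 1761 with the replicate block, 20 without those 3 libraries and 108 to 959 without 1 library; the 404 beta genes became 1297, 3477, 205, 2017, 19 and 128 to 807. Lists past the threshold fell from 8, 8 and 11 to 0 with an estimated correlation, were 7, 8 and 10 with the replicate block, and without 1 library ranged over 4 to 8, 5 to 9 and 8 to 11. For genes with H3K27me3 in beta alone (median 0.42) fry did not pass, and the preset correlation and the replicate block (adjusted p = 0.0475) did; for genes bivalent in alpha alone (-0.15) or beta alone (0.36) only the preset correlation did.

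H3K27me3 promoters in alpha minus beta went from 388 to 975 with the better-scoring part of each list and 948 with equally long lists. Islet minus exocrine went from -337 to -540 with a window of 2500 bp, which passed, and to 146 with equally long lists. H3K4me3 promoters in alpha alone numbered 50, and 150 at the start itself, 77 with equally long lists, 485 with 3 of 4 against at most 1 and 53 to 1.6e+02 (rounded) without 1 library; in beta alone 1, and 2 with the wide window, 0 with the large overlap, 5 with the better-scoring part, 29 with 3 of 4 against 1, 10 without the donor with both marks and 1 to 3 without 1 library. H3K27me3 promoters in alpha alone numbered 386, and 584 with equally long lists and 675 with 2 of 3; in beta alone 264, and 169 with the better-scoring part and 472 with 2 of 3. The bivalent difference of 888 lost its p with the better-scoring part (265), the replicate block (888, exact p = 0.125), without the donor with both marks in H3K4me3 (517) or in either mark (439), with trimmed lists (194), and without any 1 of the beta H3K4me3 or alpha H3K27me3 libraries (510 to 1152 over all libraries). By the H3K4me3 of 1 donor it was 300, 2085 and 273 in those that moved. The H3K4me3 similarity difference of 0.0177 ranged from -0.0129 to 0.0744 without 1 library. With a pseudocount of 0.1 the alpha difference between bivalent and H3K27me3 genes moved to 0.50, the beta difference between H3K4me3 and bivalent genes to 1.23 and the exocrine differences to 1.47 and 0.54, and with 1 the exocrine one to 0.87.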

Other observations

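Fisher's exact tests of list overlap were chosen after the data were seen, and the genes below were picked after their values were seen.

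TGF-beta pathway genes differed between islet and exocrine cells in both assays. Of the 5 pathway promoters with H3K27me3 in every islet cell and no exocrine library, ID3, a target of BMP signalling, was also lower in RNA in both islet cell types, at 1.34 RPKM in alpha and 13.4 in exocrine cells (alpha against exocrine -2.91, limma adjusted p = 0.0017; beta against exocrine -2.79, adjusted p = 0.002). TGFBR2, a TGF-beta receptor gene, at 1.22 in alpha, 0.839 in beta and 3.27 in exocrine cells, passed in beta (-1.52, adjusted p = 0.0348) and not in alpha cells (-1.19, adjusted p = 0.0953). The list as a whole went both ways, with fry's mixed test at an adjusted p of 8.6e-05 and camera at 0.414 for beta against exocrine cells. That mixed test also passed for the beta cell, acinar, duct, stress, HOX and neuronal lists, so it was not particular to this list. GREM1, a BMP antagonist gene, had a log2 fold change of 1.55 between beta and exocrine cells. It passed when adjusted over the list alone and not over all genes (limma adjusted p = 0.106). In beta cells 4 genes of the list were lower over all genes, which also included BMP2 and SMAD3, and in alpha cells 2 were, ID3 and SMAD3.

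DPP4, GCG and FAP are neighbours on chromosome 2 between 162557001 and 162808291, and each promoter had H3K27me3 in 3 of 3 beta and 0 of 3 alpha libraries. In exocrine cells GCG and DPP4 had the mark in 3 of 3 libraries and FAP in 0 of 3. All 3 had higher mean RNA in alpha than in beta cells, with log2 fold changes of 2.25, 4.73 and 2.83, none past the threshold over all genes. Promoters bivalent in both alpha and beta cells held 5 stress response genes, ATF3, CXCL2, FOSB, MYC and SOCS3, of 8 with H3K27me3 in both types (1.37 expected, adjusted p = 0.103, one-sided Fisher's exact test).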
